A study of Mus musculus with 12 samples.

How the data were processed

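Gene expression was measured in 12 mouse stem cell samples, 3 each of wild type, Lin28a loss, Lin28b loss and loss of both genes, with 1 Illumina WG-6 BeadChip array per sample. Groups were taken from the phenotype in the labels, and samples are named here by group and replicate. The array positions in the labels put wild type and Lin28a loss on 1 chip, called chip 1, and Lin28b loss and double loss on the other, called chip 2. The sample titles give each genotype 1 line name, and nothing in the labels says that replicates came from separate cultures. If they did not, each p-value measures only the spread between these samples. Either way, with 1 line per genotype, no p-value measures the spread between lines of a genotype. Line and genotype therefore cannot be told apart in any comparison. The labels call the tissue embryonic stem cells, while the series design calls the controls wild-type iPS cells; all were grown in medium with serum and Lif, per the labels' protocols.

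The table used holds a signal and a detection p per gene and array. Each signal is the mean bead intensity on a linear scale, neither background subtracted nor normalized between arrays, per the file headers (GenomeStudio, GSGX version 1.9.0, version of GenomeStudio itself not stated). Each detection p-value, per the file headers, comes from the same export, which sets a signal against the negative control beads of its array. Above background means here a detection p under 0.01. Some bright genes missed it: Psmd8 had normalized log2 intensities of 11.18, 11.06 and 11 in Lin28a loss and passed on 2 arrays. Missing it therefore does not by itself place a signal near background. The deposited table is summarised by gene where the design had assumed probes, so each gene has 1 signal even where several probes read it. Of all columns of per-sample values 60 were not used: 48 of this table, which hold bead counts, bead errors, array numbers and array SDs, and 12 of a table described below. A further deposited table of probe-level values, which the authors normalized between arrays, gave 45281 probes of intensity that no file pairs with a gene name. These values ran from -19.6 to 39567 with 19.6% below 0, so they are on a linear scale with background subtracted. Their medians per array lay between 10.8 and 14.2 and their means between 310.0 and 442.4, and their quantiles correlated with the scanner signal of the same array at 0.999 or above. They were not centred, and have no direction to settle; no file states how the authors scaled them. Another deposited table has 12 value columns that carry only numbers, so no column name matches a sample, and it was left out. Its header names background subtraction and rank invariant normalization.

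The background of each array was estimated from the detection p of 23306 genes with a single probe, which came in steps that correspond to 936 negative control bead types (78.0% of the values checked on 1 array lay within 0.006 of a whole multiple). Signals were corrected with the normexp model in limma 3.58.1 under R 4.3.3, an offset of 16 was added, log2 was taken and arrays were quantile normalized. A gene was tested where its detection p was under 0.01 on all 3 arrays of at least 1 group. Of 30854 genes, 10372 passed, and 9920 were tested after 452 further entries of a symbol with a brighter entry were dropped. Names were brought up to date against a mouse RefSeq table (GRCm38.p6). In all, 18045 genes matched by Entrez identifier, 2073 by symbol and 2663 by synonym, and 8073 kept the name in the file. Chromosomes were those the file gives, known for 6438 of the tested genes, except in the scan for neighbouring genes with large interactions. That scan took chromosome and order from the RefSeq table, which placed 8378 genes. The order of genes along chromosome 8 came from the RefSeq table too. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

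Comparisons were made with limma's lmFit and eBayes on all 12 arrays, which share 1 estimate of the spread, and p-values were adjusted by Benjamini-Hochberg over the genes of each comparison. A gene rose or fell where its adjusted p was under 0.05. There were 8 comparisons: each loss group against wild type, double loss against each single loss, Lin28a loss against Lin28b loss, the effect of Lin28a loss with the chip as a block, and the interaction of both losses. The interaction is the effect of Lin28a loss among Lin28b-loss cells less its effect among cells with Lin28b. Each of the latter effects lies within 1 chip, so an additive chip effect cancels. For comparisons across chips, chip and genotype cannot be told apart.

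The groups, the comparisons, the gene lists, the rule for named genes and most alternative settings were fixed before the data were examined. The rule named Lin28a and Lin28b first. It then took the 10 largest rises and falls of each loss group against wild type (6 each way for the blocked effect and the interaction, 3 for the others) among genes past the threshold whose 3 arrays of a group all lay outside the range of the other group's 3, except that the interaction had no such range condition. Clone, accession and predicted-gene names were passed over. Up to 4 members of each list that passed in a comparison with wild type were added. The 19 lists were oxidative phosphorylation, glycolysis, serine, glycine and one-carbon metabolism, naive, general and primed pluripotency, reported let-7 targets, cytosolic ribosomal proteins, cell cycle, neuroectoderm, mesoderm, endoderm, trophoblast, fibroblast, germline, two-cell embryo, imprinted genes, p53 targets and the integrated stress response. Each was tested with limma's camera at a preset correlation of 0.01, with an estimated correlation beside it, and adjusted over the lists of a comparison. limma's fry was an alternative.

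A gene that no array of a group detected has only a bound there. Its difference is then given as "at least N-fold": the brighter group's mean over the dimmer group's mean of, per array, the higher of the gene's own value and the lowest value among detected genes, all as normalized log2 values. With 3 arrays a group, the number of arrays limits the precision. The steps were tested on simulated data made from the means and SDs of these arrays, with noise drawn for each gene on its own and 50 genes changed at each size. For Lin28a loss against wild type, 8.00%, 62.0%, 96.0% and 100.0% of the genes changed by 1.2, 1.5, 2 and 4 times were called among 9920 genes, and 18 unchanged genes were, which is 11.2% of the calls. For the interaction the shares were 2.00%, 18.0%, 80.0% and 100.0%, with 8 unchanged genes called. A list made to shift was called in each of the 8 comparisons and no other list was. Simulated genes were uncorrelated, while in the real arrays 54.7% of the variance of within-group deviations lay on their first component. The simulation therefore cannot show how often genes or lists are called falsely where genes vary together.

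Alternatives were: no background correction, an offset of 50, median scaling or cyclic loess between arrays, no filter or detection on all 12 arrays, only the arrays compared, a trended robust prior, fold thresholds (2-fold, or limma's treat against 1.2), the replicate number as a block, 1 mean per group in place of the chip term, every entry of the table or another entry of the same gene (the plan named probes, which a gene-level table does not give), the authors' probe values floored at 16, and each array left out in turn. After the data were seen, 4 were added: without the brightest array of 3 groups, the log2 mean raw signal as a covariate, limma's array weights, and without the genes of chromosome 8.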

Results

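Expression was compared among 12 mouse pluripotent stem cell samples in 4 groups of 3: wild type, loss of Lin28a, loss of Lin28b and loss of both paralogs. Lin28 proteins bind RNA and keep the microRNA let-7 from maturing, and the series title names overlapping and distinct roles of the paralogs as its subject. Mean raw signal per array ranged from 325.4 to 596.7, and between 9377 and 10773 genes per array were above background. The brightest array of wild type, of Lin28a loss and of double loss deviated from its group in a common way (r of deviations across genes, which are not independent replicates, 0.458 to 0.686). Without these 3 arrays 5030 genes differed between Lin28a loss and wild type, 4847 between Lin28b loss and wild type, and 4367 between double loss and wild type, against 3645, 3581 and 3676 with them. The Y-linked gene Eif2s3y was above background on all 3 arrays of Lin28b loss (log2 7.21 ± 0.29, SD) and of double loss (6.15 ± 0.18) and on none of wild type (4.64 ± 0.12) or Lin28a loss (4.54 ± 0.08). Xist was not above background in any group.

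Lin28a itself was measured first. Its normalized log2 intensity was 8.02 ± 0.11 (SD, n = 3) in wild type, 5.69 ± 0.08 in Lin28a loss, 7.08 ± 0.17 in Lin28b loss and 5.51 ± 0.17 in double loss, and each of the 12 arrays was above background. Lin28a fell by 2.33 ± 0.11 (SE) on the log2 scale in Lin28a loss against wild type (limma, adjusted p = 1.53e-08) and fell by 2.51 ± 0.11 in double loss (adjusted p = 7.88e-09). With the chip as a block, Lin28a fell by 1.95 ± 0.14 where its loss was compared (adjusted p = 2.19e-06), and within chip 2 by 1.57 ± 0.11 (adjusted p = 6.75e-07). Lin28a also fell by 0.94 ± 0.11 in Lin28b-loss cells, across chips (adjusted p = 4.85e-05). The part of Lin28a that the probes read, and whether it was deleted, is not given. Lin28b was above background in no group, wild type included, by either of its entries in the file, so its loss could not be checked here.

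**Figure D1:**
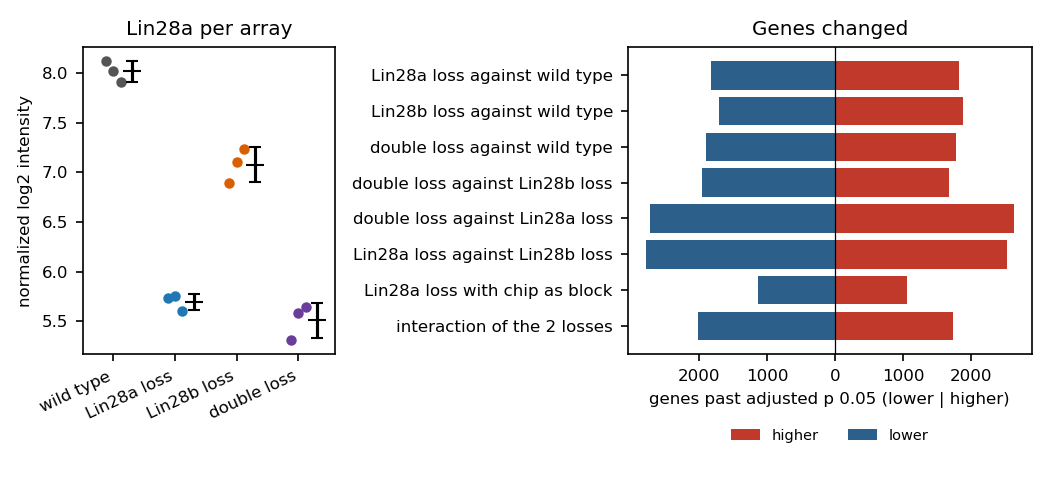
Left, normalized log2 intensity of Lin28a on each array by group, where points are arrays and the dash and bar are the mean and SD of 3 arrays. Right, the number of genes that were higher or lower at an adjusted p under 0.05 in each comparison, from 2189 with the chip as a block to 5348 between double loss and Lin28a loss.

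Lin28a loss with Lin28b intact was compared with wild type within chip 1, where chip does not enter but line and genotype cannot be told apart. Otx2, a transcription factor of the exit from naive pluripotency, fell by 2.89 ± 0.13 (SE, n = 3 per group here and below) on the log2 scale (adjusted p = 5.09e-09). Zfp42, a marker of naive cells, fell by 2.09 ± 0.11, the growth factor gene Bmp4 fell by 2.15 ± 0.10 (1 of its 3 Lin28a-loss arrays above background), and Sp5, a Wnt target, fell by 2.32 ± 0.27 (2 of 3). Uap1, an enzyme of amino sugar synthesis, fell by 3.12 ± 0.17, and the imprinted RNA Meg3 fell by 2.86 ± 0.22. Higher in Lin28a loss were the proteasome subunit Psmd8 (log2 fold change 3.93 ± 0.23, with 2 of 3 arrays passing detection in each group) and Nod1, a sensor of bacterial peptides (3.24 ± 0.13, with 1 wild-type array above background). Olig1, a transcription factor of oligodendrocyte precursors, was not above background in wild type and was at least 25.4-fold higher in Lin28a loss (adjusted p = 2.38e-11). Pdrg1, Obox6 and Zfp365, also at background in wild type, were at least 10.8-, 8.94- and 5.99-fold higher (adjusted p = 1.23e-12, 2.25e-10 and 2.68e-11). On no array of double loss, where Lin28a is lost too, was any of them above background.

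In total 3645 of 9920 genes changed with Lin28a loss, 1818 up and 1827 down, of which 541 changed at least 2-fold (380 up, 161 down). Under median scaling 1408 changed, 987 up and 421 down. Several of the largest changes were of genes on chromosome 17 in or near the H2 region. H2-Bl, Abhd16a and Wdr46 were at least 10.4-, 15.3- and 9.02-fold higher (adjusted p = 6.71e-10, 6.26e-10 and 5.57e-10), and H2-Q6 was at least 3.87-fold lower (adjusted p = 7.68e-09). The median log2 fold change of 376 genes on chromosome 8, where Zfp42 and the list members Herpud1, Dpep3, Col4a2 and Mmp2 lie, was 0.23 against -0.04 for genes of all other chromosomes.

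Stress-response and germline genes stood higher in Lin28a loss. Of 20 measured members of the integrated stress response list, 14 rose and 2 fell (16 changed adjusted over the list alone), among them Nupr1 (log2 fold change 1.48 ± 0.16), Chac1, which degrades glutathione (1.28 ± 0.17), Ddit3, which encodes the stress factor CHOP (1.23 ± 0.31), and Herpud1 (1.11 ± 0.11). The list rose (camera adjusted p = 4.14e-04), with adjusted p = 0.10 with an estimated correlation. Of 9 measured germline genes, 7 rose and none fell (8 adjusted over the list alone), with Piwil2 at 0.90 ± 0.10, Fkbp6 at 0.97 ± 0.20 and Dpep3 at least 1.9-fold higher (adjusted p = 4.98e-07). The germline list rose (adjusted p = 4.14e-04; adjusted p = 0.10 with an estimated correlation, and 0.083 with the 2 members detected on all 12 arrays).

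Trophoblast, general and primed pluripotency and let-7 target genes stood lower in Lin28a loss. Of 8 trophoblast genes 6 fell (6 adjusted over the list alone), with Rhox9 at -1.81 ± 0.20, the keratin Krt8 at -0.79 ± 0.09 and Rhox6 at least 2.72-fold lower (adjusted p = 8.21e-06). The list fell (adjusted p = 0.0070; adjusted p = 0.24 with an estimated correlation). Among 24 reported let-7 targets 9 fell and 1 rose (11 adjusted over the list alone), with Nr6a1 at -1.08 ± 0.09, Plagl2 at -0.76 ± 0.11 and Slc20a1 at 0.72 ± 0.12. This list fell (adjusted p = 0.015; adjusted p = 0.16 with an estimated correlation). Of 17 general pluripotency genes 7 fell and 1 rose (10 adjusted over the list alone), Lefty1 by -1.47 ± 0.21 and Utf1 by -0.67 ± 0.12, and the list fell (adjusted p = 0.018; adjusted p = 0.24 with an estimated correlation). Of 11 primed pluripotency genes 6 fell and 1 rose (8 adjusted over the list alone), Otx2 first, then Lefty2, an inhibitor of Nodal signalling (-1.48 ± 0.19), and Zic2 (-1.12 ± 0.13, with 1 Lin28a-loss array above background). That list fell (adjusted p = 0.038; adjusted p = 0.23 with an estimated correlation, and 0.053 without a filter on dim genes).

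The other 13 lists did not pass in Lin28a loss (adjusted p from 0.11 to 0.99). Members of 20 naive pluripotency genes went both ways, 5 up and 5 down (10 adjusted over the list alone), with Jam2 at 1.82 ± 0.18, Nr5a2 at -1.36 ± 0.13 and Dppa3 at -1.31 ± 0.14. So did 5 up and 5 down of 15 imprinted genes (10 adjusted over the list alone), with Ndn at 1.62 ± 0.12, Igf2 at -1.41 ± 0.16 and H19 at -1.23 ± 0.24. Of 18 genes of serine, glycine and one-carbon metabolism 5 rose and 3 fell (8 adjusted over the list alone), including Ahcy (1.77 ± 0.12, with 2 wild-type arrays passing detection), which clears S-adenosylhomocysteine, and Mat2a (-0.81 ± 0.15), which makes S-adenosylmethionine. Of 15 glycolysis genes 3 fell (2 adjusted over the list alone), with Pdk1 at -1.09 ± 0.08 and Eno1 at -0.83 ± 0.10. Of 10 endoderm genes 5 rose and 1 fell (6 adjusted over the list alone), with Sparc at 1.40 ± 0.08, and the list passed as higher among genes detected on all 12 arrays (0.015). Oxidative phosphorylation had 1 rise and 4 falls among 63 genes (0 adjusted over the list alone), ribosomal proteins 3 and 1 among 51 (4), cell cycle 0 and 5 among 25 (4), p53 targets 3 and 1 among 16 (4), mesoderm 1 and 3 among 8 (4), fibroblast 2 and 3 among 6 (5), neuroectoderm 1 and 1 among 4 (2), and the two-cell list 0 and 0 with 1 gene measured (0).

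Lin28b loss with Lin28a intact was compared with wild type across chips, so neither chip nor line can be told apart from genotype. Otx2, which fell in Lin28a loss, rose by 2.66 ± 0.13 (SE) on the log2 scale (adjusted p = 1.13e-08), and the growth factor gene Nodal by 1.0 ± 0.11. The cell adhesion gene Jam2 rose by 3.04 ± 0.18, the surface antigen gene Ly6a by 3.25 ± 0.12 (2 of 3 wild-type arrays above background) and Nod1 by 4.26 ± 0.13. Prdm14, a regulator of naive pluripotency and the germline that was not above background in wild type, was at least 2.73-fold higher (adjusted p = 4.02e-07). Lower were H19, an imprinted RNA, which fell by 3.63 ± 0.24 (2 of 3 Lin28b-loss arrays above background), and Meg3, which fell by 2.74 ± 0.22. Gbx2, a factor of naive self-renewal, fell by 2.58 ± 0.18, and Zfp42 fell by 1.69 ± 0.11. Lars2, the mitochondrial leucyl-tRNA synthetase, was at least 4.83-fold lower (adjusted p = 1.25e-09), and Wdr82 was at least 7.65-fold lower by its brighter entry, while its other entry was higher (0.21). In double loss, where Lin28b is lost too, Lars2 read log2 7.91, 7.87 and 7.88, against 7.99, 7.89 and 7.91 in wild type.

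In total 3581 genes changed with Lin28b loss, 1875 up and 1706 down, of which 495 changed at least 2-fold (242 up, 253 down). Median scaling, which aligns medians over all 30854 genes, moved the median of the 9920 tested genes to -0.22. Raw medians per array ran from 47.4 to 75.2, near the inferred negative control means of 41.97 to 61.18. Median scaling gave 1733 changed genes, 393 up and 1340 down, while array weights gave 5672. Wdr46, Abhd16a and Ubd, on chromosome 17, were at least 13.3-, 15.9- and 6.41-fold higher (adjusted p = 3.30e-10, 9.37e-10 and 5.64e-09). The median of the 376 genes of chromosome 8, which holds Zfp42, was 0.24 against -0.03 for other chromosomes.

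Stress-response and respiratory chain genes stood lower in Lin28b loss. Of 20 genes of the integrated stress response list 10 fell and 1 rose (11 adjusted over the list alone), with Chac1 at -1.19 ± 0.17, Nupr1 at -1.12 ± 0.16 and the seryl-tRNA synthetase Sars at -1.01 ± 0.11. The list fell (adjusted p = 0.0054; adjusted p = 0.35 with an estimated correlation). Of 63 oxidative phosphorylation genes 13 fell and none rose (9 adjusted over the list alone), with Sdhd of complex II at -0.74 ± 0.15 and Ndufb5 of complex I at -0.64 ± 0.12. This list fell (adjusted p = 0.012; adjusted p = 0.37 with an estimated correlation). The trophoblast list, with 5 falls and 1 rise among 8 genes (7 adjusted over the list alone; Krt18 at -1.14 ± 0.13), missed the threshold at adjusted p = 0.052. It passed under median scaling (0.038), cyclic loess (0.046), or without wild-type replicate 1 (0.012) or 3 (0.041), Lin28b-loss replicate 1 (0.028) or double-loss replicate 3 (0.018). The germline list, with 5 falls and 1 rise among 9 (6 adjusted over the list alone; Piwil2 at -1.43 ± 0.10), also gave 0.052, and passed without wild-type replicate 3 (0.031), Lin28a-loss replicate 1 (0.042) or Lin28b-loss replicate 1 (0.028).

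The other 15 lists had adjusted p from 0.099 to 0.65 in Lin28b loss. Of 18 genes of serine, glycine and one-carbon metabolism 8 fell and 1 rose (9 adjusted over the list alone), with Psat1 at -1.47 ± 0.26 and Phgdh at -1.05 ± 0.13, enzymes of the first steps of serine synthesis. Of 11 primed pluripotency genes 5 rose and 2 fell (7 adjusted over the list alone), and the list passed under median scaling (0.046). Of 20 naive pluripotency genes 8 rose and 4 fell (12 adjusted over the list alone), and of 17 general ones 2 rose (2). Imprinted genes had 3 rises and 6 falls among 15 (9 adjusted over the list alone), with Igf2 at -1.69 ± 0.16. Ribosomal proteins had 5 rises and 2 falls among 51 (5 adjusted over the list alone), with Rps3a1 at -1.89 ± 0.13 and Rps15a at 1.08 ± 0.10, and the list passed as higher than other genes under median scaling (0.010, with 1 rise and 3 falls) and cyclic loess (0.0020, with 24 rises and 2 falls). Among 24 let-7 targets 2 rose and 4 fell (6 adjusted over the list alone), with Cdc25a at -0.75 ± 0.09. Glycolysis had 7 rises and 1 fall among 15 (8), cell cycle 5 and 2 among 25 (7), p53 targets 0 and 4 among 16 (4; Cdkn1a at -0.97 ± 0.10), mesoderm 3 and 2 among 8 (5), endoderm 3 and 3 among 10 (6), neuroectoderm 2 and 0 among 4 (2), fibroblast 1 and 0 among 6 (1), and the two-cell list 0 of 1 (0), where numbers in parentheses are adjusted over the list alone.

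Loss of both paralogs against wild type, again across chips that cannot be told apart from genotype, gives what differed when both genes were targeted. Ctsc, a lysosomal protease, fell by 4.90 ± 0.12 (SE) on the log2 scale (adjusted p = 3.28e-11; 1 double-loss array above background). Of the imprinted genes, H19 fell by 4.27 ± 0.24 (1 double-loss array above background), the growth factor gene Igf2 fell by 2.54 ± 0.16 and Meg3 fell by 2.70 ± 0.22. Pclaf, a partner of PCNA in DNA replication, fell by 2.70 ± 0.12. Tomm22, part of the mitochondrial import pore, rose by 4.33 ± 0.09 (adjusted p = 2.48e-11), Psmd8 by 3.96 ± 0.23 (2 of 3 arrays passing detection in each group) and the transcription factor gene Msc by 3.11 ± 0.22. Cdhr1 and Prdm14, at background in wild type, were at least 6.05- and 2.84-fold higher (adjusted p = 5.12e-10 and 3.04e-07). Picalm, an adaptor of clathrin-mediated uptake, was at least 9.61-fold lower (adjusted p = 2.97e-10). Ctsc and Picalm lie in 1 block of 50 neighbouring genes of chromosome 7. That block held 5 interactions of at least 4-fold, where shuffled positions gave 7 at most. Whether the falls of Ctsc and Picalm are separate was not tested.

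In total 3676 genes changed with loss of both, 1777 up and 1899 down, of which 559 changed at least 2-fold (273 up, 286 down). Median scaling moved the median of the tested genes to -0.13 and gave 1723, 471 up and 1252 down, while array weights gave 5746. On chromosome 8 the median was -0.10.

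Trophoblast genes stood lower in double loss and p53 targets higher. Of 8 trophoblast genes 6 fell and none rose (6 adjusted over the list alone), with Rhox9 at -1.88 ± 0.20, Krt18 at -1.44 ± 0.13 and Krt7 at -1.32 ± 0.13 (2 double-loss arrays above background). The list fell (adjusted p = 3.25e-04; adjusted p = 0.24 with an estimated correlation). Of 16 p53 targets 8 rose and none fell (8 adjusted over the list alone), with Plk2, a kinase induced by stress, at 1.16 ± 0.14. This list rose (adjusted p = 0.042; adjusted p = 0.24 with an estimated correlation). Its call was lost among genes detected on all 12 arrays (0.14), in a fit of the 6 arrays compared (0.053), and without wild-type replicate 3 (0.084) or double-loss replicate 1 (0.053), 2 (0.065) or 3 (0.051).

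The other 17 lists had adjusted p from 0.18 to 0.97 in double loss. Pluripotency genes went both ways: of 20 naive ones 8 rose and 4 fell (12 adjusted over the list alone), with Jam2 at 2.89 ± 0.18, Nr5a2 at 1.42 ± 0.13 and Gbx2 at -2.41 ± 0.18, and of 11 primed ones 3 rose and 4 fell (7), with Otx2 at 2.01 ± 0.13, Nodal at 1.35 ± 0.11 and the DNA methyltransferase Dnmt3b at -1.14 ± 0.10. Among 17 general ones 6 rose (6 adjusted over the list alone). Among 24 let-7 targets 3 rose and 6 fell (9 adjusted over the list alone), with Nr6a1 at -1.56 ± 0.09 and Arid3b at -0.84 ± 0.12. The integrated stress response list had 3 rises and 6 falls among 20 (9 adjusted over the list alone), with Chac1 at -1.82 ± 0.17 and Ddit4 at -1.63 ± 0.17. Imprinted genes had 2 rises and 6 falls among 15 (8 adjusted over the list alone), with Ndn at 1.33 ± 0.12, and that list passed as lower under median scaling (0.022), where ribosomal proteins passed as higher than other genes (0.022, with 2 rises and 2 falls). Glycolysis had 1 rise and 3 falls among 15 (4), with Eno2 at -1.61 ± 0.15 and Pdk1 at -0.92 ± 0.08. Serine, glycine and one-carbon metabolism had 4 and 7 among 18 (11), oxidative phosphorylation 1 and 5 among 63 (0), ribosomal proteins 3 and 2 among 51 (5), cell cycle 7 and 1 among 25 (8), mesoderm 2 and 4 among 8 (7), endoderm 3 and 2 among 10 (7), neuroectoderm 1 and 2 among 4 (4), fibroblast 3 and 1 among 6 (4), germline 3 and 2 among 9 (5), and the two-cell list 0 of 1 (0), again with numbers adjusted over the list alone in parentheses.

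**Figure D2:**
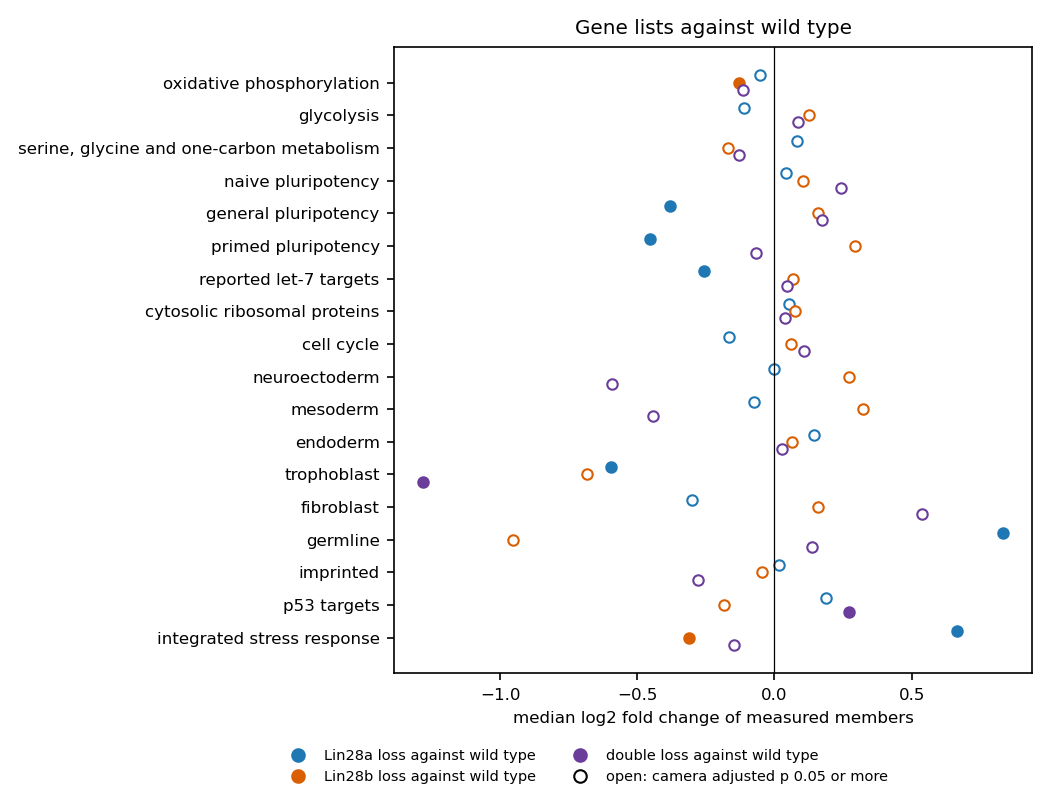
Median fitted log2 fold change (horizontal axis) of the measured members of 18 gene lists in the 3 loss groups against wild type. Filled points mark a camera adjusted p under 0.05 at the preset correlation, and open points mark 0.05 or more. The integrated stress response lies above 0 in Lin28a loss and below 0 in the other groups.

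**Figure D3:**
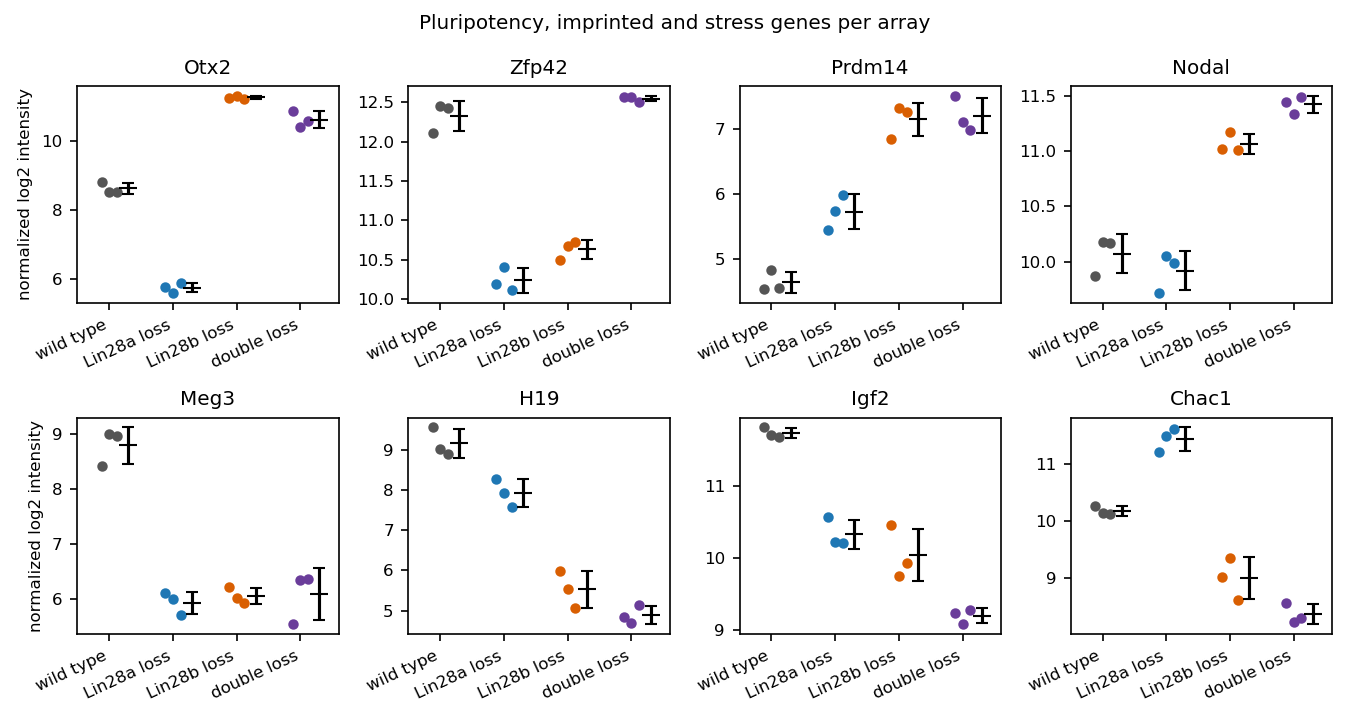
Normalized log2 intensity on each array, by group, of 8 genes named in the text; points are arrays, and the dash and bar are the mean and SD of 3 arrays. Otx2 averaged 8.63 in wild type, 5.74 in Lin28a loss, 11.29 in Lin28b loss and 10.64 in double loss, while Meg3, H19 and Igf2 were lower in all 3 loss groups than in wild type. Prdm14 was not above background in wild type.

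The effect of Lin28a loss was also measured where Lin28b was already lost, as double loss against Lin28b loss within chip 2. Tomm22 rose by 4.54 ± 0.09 (SE) on the log2 scale (adjusted p = 6.98e-12) and Cyp2c70, a bile acid hydroxylase, by 3.97 ± 0.14 (1 Lin28b-loss array above background), while Ctsc fell by 4.27 ± 0.12. Abhd16a and Wdr46 were at least 16.2- and 13.5-fold lower (adjusted p = 6.39e-10 and 2.95e-10). Of 16 p53 targets 10 rose and none fell (11 adjusted over the list alone), with Plk2 at 1.59 ± 0.14, Aen, an apoptotic nuclease, at 1.13 ± 0.09 and the cell cycle inhibitor Cdkn1a at 1.10 ± 0.10, members picked after their values were seen. The p53 list rose (adjusted p = 8.73e-04) and kept its call at adjusted p = 0.045 with an estimated correlation, the only one of the lists called in the 8 comparisons to do so.

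Within chip 2, 3621 genes changed, 1669 up and 1952 down, of which 494 changed at least 2-fold (241 up, 253 down); under median scaling 1228 did, and with array weights 5738. Of the 376 genes of chromosome 8, 21 rose and 189 fell within chip 2 (median -0.33). Trophoblast genes had 4 falls and no rise among 8 (4 adjusted over the list alone; adjusted p = 0.037, and adjusted p = 0.34 with an estimated correlation). Germline genes had 5 rises and 1 fall among 9 (6 adjusted over the list alone; adjusted p = 0.037, and adjusted p = 0.30 with an estimated correlation). The trophoblast call was lost without wild-type replicate 1 (0.16), Lin28b-loss replicate 1 (0.068) or double-loss replicate 1 (0.064) or 3 (0.12), and the germline call without wild-type replicate 1 (0.055), Lin28a-loss replicate 3 (0.068) or double-loss replicate 1 (0.060). Without the 3 brightest arrays they gave 0.32 and 0.12. The germline call was also lost under median scaling (0.090), with an offset of 50 (0.069), without background correction (0.069) and with the 2 members detected on all 12 arrays (0.97), and the trophoblast call without a filter on dim genes (0.24). With array brightness as a covariate both gave 0.057, and with array weights 0.095 and 0.063. The other 16 lists had adjusted p from 0.070 to 1.0, with cyclic loess calling glycolysis (0.021, lower) and ribosomal proteins (0.021, lower) and median scaling oxidative phosphorylation (0.0050, higher).

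With the chip as a block, the effect of Lin28a loss averaged over both backgrounds passed in 2189 genes, 1051 up and 1138 down, of which 209 changed at least 2-fold (151 up, 58 down). A fit with 1 mean per group in place of the chip term gave 3736. That fit averages the same within-chip differences, so an additive chip effect cancels there too, but the interaction no longer counts as spread. With the chip as a block, array weights gave 3296 and median scaling 793, 555 up and 238 down. Tomm22 rose by 3.72 ± 0.24 (adjusted p = 1.46e-06) and Sord, the enzyme that oxidizes sorbitol, by 2.43 ± 0.25 (adjusted p = 5.26e-05; 2 wild-type arrays above background). Otx2 fell by 1.77 ± 0.33 (adjusted p = 0.0028) and the membrane protein gene Tmem64 fell by 1.6 ± 0.14 (adjusted p = 1.12e-05). Lists that rose were germline (8 of 9 genes up; 8 adjusted over the list alone; adjusted p = 8.30e-05, and adjusted p = 0.068 with an estimated correlation), the integrated stress response (9 up and 2 down of 20; 14; 1.69e-04, and adjusted p = 0.068 with an estimated correlation) and p53 targets (7 of 16 up; 8; 9.41e-04, and adjusted p = 0.11 with an estimated correlation). Lists that fell were trophoblast (5 of 8 down; 5; 5.66e-04, and adjusted p = 0.094 with an estimated correlation), primed pluripotency (6 of 11 down; 6; 0.017, and adjusted p = 0.094 with an estimated correlation), glycolysis (3 down and 1 up of 15; 6; 0.018, and adjusted p = 0.18 with an estimated correlation) and let-7 targets (5 down and 1 up of 24; 6; 0.038, and adjusted p = 0.18 with an estimated correlation). The germline call was lost with only the 2 members detected on all 12 arrays (0.16). The let-7 call was lost without wild-type replicate 1 (0.062), 2 (0.063) or 3 (0.066) or Lin28a-loss replicate 1 (0.074) or 2 (0.072), among genes detected on all 12 arrays (0.062) and without a filter on dim genes (0.065), which also ended the call of primed pluripotency (0.051). The other 12 lists had adjusted p from 0.10 to 0.91; general pluripotency, at 0.10, passed as lower without Lin28b-loss replicate 1 (0.045) or without a filter on dim genes (0.016).

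Double loss against Lin28a loss and Lin28a loss against Lin28b loss, both across chips that cannot be told apart from genotype, gave 5348 and 5302 changed genes (2620 up and 2728 down, and 2520 up and 2782 down). At least 2-fold changes numbered 1118 and 1091. Median scaling moved the median of the tested genes to -0.14 and 0.23. It gave 3194 (841 up, 2353 down) and 3187 (2491 up, 696 down). Otx2 rose by 4.90 ± 0.13 in double loss against Lin28a loss (adjusted p = 3.30e-11) and fell by 5.55 ± 0.13 in Lin28a loss against Lin28b loss (adjusted p = 1.24e-11). In double loss against Lin28a loss, Cyp2c70 and Sall3, a zinc finger factor of development, were at least 17.2- and 10.6-fold higher (adjusted p = 1.03e-10 and 6.51e-09), Ctsc fell by 5.4 ± 0.12, and Olig1 was at least 25.9-fold lower (adjusted p = 2.61e-11). There the integrated stress response list had 14 falls and 3 rises among 20 genes (17 adjusted over the list alone) and fell (adjusted p = 0.0059; adjusted p = 0.33 with an estimated correlation). Germline genes had 6 falls among 9 (6 adjusted over the list alone; 0.017), general pluripotency 9 rises among 17 (9; 0.016) and cell cycle 16 rises among 25 (17; 0.019). For these, adjusted p = 0.33, 0.33 and 0.39 with an estimated correlation, in that order, and the cell cycle call was lost without double-loss replicate 1 (0.071). Lin28a loss against Lin28b loss had higher integrated stress response (15 up, 2 down of 20; 17 adjusted over the list alone; adjusted p = 4.79e-05) and germline genes (8 up, 1 down of 9; 9; 3.55e-04), each at adjusted p = 0.088 with an estimated correlation. Lower were general pluripotency (11 of 17 down; 11; 0.012), glycolysis (8 down, 1 up of 15; 11; 0.015) and primed pluripotency (7 down, 1 up of 11; 8; 0.026), with adjusted p = 0.23, 0.32 and 0.23 with an estimated correlation, in that order. Among genes detected on all 12 arrays the germline calls of both comparisons were lost (0.26 and 0.36). The remaining lists ran from 0.17 to 0.66 in the former and from 0.10 to 0.92 in the latter.

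The interaction compares the effect of Lin28a loss with and without Lin28b, where each effect lies within 1 chip. With 1 line per genotype, it cannot tell a dependence on Lin28b from differences between lines. For Zfp42 and Ly6e, a surface antigen gene, either single loss stood below wild type while double loss did not. Zfp42 averaged log2 12.33 in wild type, 10.24 in Lin28a loss, 10.64 in Lin28b loss and 12.55 in double loss, an interaction of 4.0 ± 0.16 (SE, adjusted p = 2.48e-09). Ly6e averaged 10.86, 9.21, 9.13 and 11.37 in the same order (interaction 3.90 ± 0.23, adjusted p = 1.10e-07). Nod1 was the other way round, at 5.52, 8.76, 9.78 and 6.02 (interaction -7.00 ± 0.19, adjusted p = 5.13e-11). Olig1, Abhd16a, Wdr46, Ubd and H2-Bl were likewise above background in both single losses and in neither wild type nor double loss (adjusted p from 1.33e-11 to 9.72e-10), and the last 4 of these lie on chromosome 17. In total 3748 genes had an interaction, 1732 above 0 and 2016 below, and under median scaling 1470. The genes of chromosome 8 had a median interaction of -0.59. None of the 19 lists passed (adjusted p from 0.28 to 0.93), although median scaling called oxidative phosphorylation (0.0094), general pluripotency (0.042), cell cycle (0.041) and p53 targets (0.042), all above 0.

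**Figure D4:**
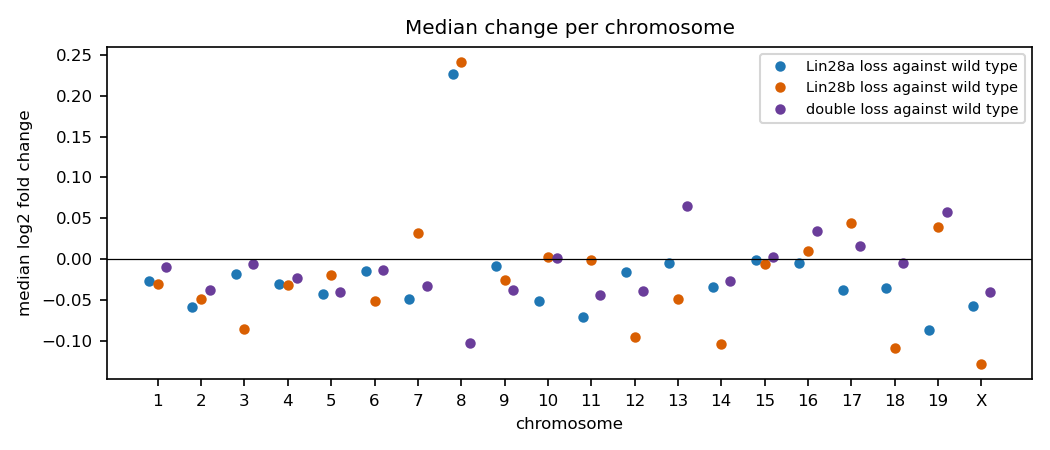
Median log2 fold change (vertical axis) of the measured genes of each chromosome in the 3 loss groups against wild type. Chromosome 8 lies at 0.23 in Lin28a loss and 0.24 in Lin28b loss, and at -0.10 in double loss, while other chromosomes lie between -0.13 and 0.07 over the 3 groups.

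How far the paralogs' effects overlap was measured by genes called in both single losses. Lin28a loss and Lin28b loss shared 885 genes in the same direction, 489 up and 396 down, and 719 in opposite directions, where independent lists would give 658 of each. Without the 3 brightest arrays the same-direction count was 1490, with array weights 1733, and under median scaling 264. Both use the same wild-type arrays, too few to split, so part of the excess may come from those. Of 376 genes of chromosome 8, 152 rose and 26 fell in Lin28a loss, and 148 rose and 32 fell in Lin28b loss. Part of the shared rises may therefore come from that chromosome. The log2 fold changes correlated across genes at r = 0.166 (rho = 0.056), where unchanged groups simulated against those arrays gave a mean of 0.429 and a range from -0.507 to 0.921, with no genes called. Their covariance exceeded the simulated one by 0.0357. Meg3, Igf2 and H19 fell and Psmd8, Jam2 and Nod1 rose in both, while Otx2, Chac1 and Nupr1 passed in opposite directions. Lin28a loss and double loss shared 939 genes in the same direction and 760 in opposite ones (675 of each for independent lists; r = 0.180, simulated mean 0.487, covariance difference 0.0400). Lin28b loss and double loss, which also share a chip, had 1697 and 238 (662 and 665 for independent lists; r = 0.542, simulated mean 0.475, covariance difference 0.136). The within-chip effects of Lin28a loss with and without Lin28b share no arrays, and had 861 genes in the same direction and 793 in opposite ones (665 of each for independent lists; r = 0.021, covariance difference 0.0043). The effects of Lin28b loss with and without Lin28a, both across chips, had 1740 and 570 (964 and 966 for independent lists; r = 0.293, covariance difference 0.1002).

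The median and mean of a list's members differed in sign for naive pluripotency and imprinted genes in Lin28a loss, for let-7 targets and mesoderm in Lin28b loss, and for glycolysis, primed pluripotency, let-7 targets and germline genes in double loss. They also differed for naive pluripotency within chip 2, for oxidative phosphorylation, naive pluripotency and fibroblast genes with the chip as a block, for one-carbon metabolism and mesoderm in double loss against Lin28a loss, for ribosomal proteins in Lin28a loss against Lin28b loss, and for naive pluripotency in the interaction. For endoderm within chip 2 and imprinted genes in the interaction the test had the opposite sign to both. None of these lists was called at the preset correlation in the comparison named.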

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

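The splits of the samples were fixed before their results were seen; the tests of the H2 region, of noise between arrays and of differences between lines were chosen only after, and the brightest arrays were left out after the data were seen.

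By the interaction term, the effect of Lin28a loss differed between the lines with and without Lin28b for 3748 genes, 37.8% of those tested. Each genotype had 1 line. It did so for 115 of the 169 genes that the rule for named genes picked. That rule took the largest changes in these data, the interaction included, so it favours such genes and their share adds no support. The genes with the largest interaction each way are given here as log2 interactions: Cyp2c70 4.91, H2-Q6 4.59, Zfp42 4.0, Wdr82 3.99, Ly6e 3.90 and Osr2 3.79, and Olig1 -9.26, Abhd16a -8.74, Wdr46 -8.43, Nod1 -7.00, Ubd -6.19 and H2-Bl -5.92. Lin28a itself had 0.76 (adjusted p = 0.0029, and 0.082 under median scaling). By its other entry Wdr82 had 0.30 (adjusted p = 0.16). Except for Zfp42, Ly6e, Nod1 and Lin28a, at least 1 group of each gene was at background, so the size depends on the offset.

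Other splits of the same arrays were counted for each result. The 6 arrays of a comparison of groups make 10 splits, 1 of which is the real one, so they are too few for a share under 0.05. The real counts were 3645, 3581, 3676, 3621, 5348 and 5302 genes in the order of the report, and the highest of the other splits gave 0 in each. For Lin28a loss with the chip as a block, 1 of 100 splits within each chip gave as many as 2189 genes, the real one, and the highest other gave 107. For the interaction 1 of 100 gave as many as 3748 and the highest other gave 1664. Splits that mix lines put the differences between lines into the spread, which lowers their counts whatever the cause. The counts thus show that arrays of a group resemble each other, and cannot exclude chance differences between single lines. For the genes changed in the same direction by both single losses, 3 of 100 splits of 9 arrays gave as many as 885. The higher ones, 1909 and 1908, took all 3 Lin28b-loss or all 3 Lin28a-loss arrays as the control group and mixed the others. Both compared groups were then mixtures of the same lines, which gives shared directions by construction. These splits therefore cannot decide whether the 885 genes exceed chance.

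The first pattern is that the sizes of the Lin28a-loss effect were nearly uncorrelated between wild-type and Lin28b-loss lines (r = 0.021 across all genes), although 861 genes changed in the same direction and 793 in opposite ones where independent lists would give 665 of each. Noise between arrays that hides a common effect is argued against by r = 0.043 across 1654 genes called in both comparisons. Array brightness is argued against by r = -0.001 across all genes without the brightest array of 3 groups. Differences between lines cannot be told apart from differences between genotypes, because each genotype has 1 line. A dependence of the Lin28a effect on Lin28b, the biological explanation the design gives, therefore stays open and was not tested apart from line.

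The second pattern is a crowd of large interactions in the H2 region of chromosome 17. A first scan in fixed blocks of 50 neighbouring genes found no block above the shuffled maximum (6 genes of at least 4-fold in each of 2 adjoining blocks, 7 at most in shuffles, and 23 of 1000 shuffles as high), and the windows used here were chosen after that. Of windows of 100 genes the highest lay in the H2 region with 13 such genes (7 on any other chromosome, 10 at most in 1000 shuffles), which is what a strain variant of the region carried by some lines may give. Against the other 10 went 3 genes, H2-K1, H2-Q5 and H2-Q6. As H2 genes, they may share signal with paralogs, so they cannot decide whether a single signal, such as interferon, moved the whole region 1 way. No list of interferon genes was tested. Signal shared between H2 paralogs cannot be told apart from such a variant, because the highest window of chromosome 17 without H2 genes held 8 genes and 51 of 1000 shuffles gave as many. A biological link to Lin28 stays open, as untested.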

How the results depend on the processing

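The settings without the brightest arrays, with brightness as a covariate, with array weights and without chromosome 8 were chosen only after the data were seen; all others were fixed before. Counts are given in the order Lin28a loss, Lin28b loss and double loss against wild type, double loss against Lin28b loss, double loss against Lin28a loss, Lin28a loss against Lin28b loss, Lin28a loss with the chip as a block, interaction, and genes changed in the same direction by both single losses. Median scaling gave 1408, 1733, 1723, 1228, 3194, 3187, 793, 1470 and 264. A 2-fold threshold gave 541, 495, 559, 494, 1118, 1091, 209, 1147 and 109, and treat against 1.2 gave 1485, 1393, 1508, 1409, 2984, 2838, 482, 2088 and 277, fewer by construction. With 1 mean per group in place of the chip term, a fit that still averages within-chip differences, the blocked count was 3736. Array weights gave 5672 for Lin28b loss, 5746 for double loss, 5738 for double against Lin28b loss, 3296 with the chip as a block and 1733 for the shared direction, and leaving out the brightest arrays gave 1490 for the latter. The authors' values, per probe with 21196 tested, gave 5936 for double loss, 5899 for double against Lin28b loss, 9323 for double against Lin28a loss, 8638 for Lin28a against Lin28b loss and 6273 for the interaction. These are counts of probes, where the main setting tested 9920 genes. As shares of what was tested they were lower than in the main setting. The cause was not tested where none is named. Every other setting kept these counts within 1.5 times. With each array left out in turn they ran from 2927 to 3857, 2804 to 3924, 3050 to 3992, 2755 to 3984, 4745 to 5663, 4494 to 5624, 1707 to 2170, 3140 to 4173 and 684 to 1020.

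Of 7230 re-evaluations of 305 values of named genes 6970 kept direction and side of the threshold, 254 lost the call and 6 reversed. The reversals were all of Wdr82, whose other entry, the one left among genes detected on all 12 arrays, gave 0.21 for Lin28b loss, -0.34 for double against Lin28b loss and -0.49 with the chip as a block. Of 3925 re-evaluations of 152 list results 3594 kept both, 67 lost the call (28 of them with an estimated correlation), 140 gained one and 124 changed sign without a call. Most gains came with fry or without a filter on dim genes, and were left out of the report except where named.

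Over all groups the replicate numbers did not pair the samples. Of 18 same-numbered pairs across groups 9 had a correlation of deviations above 0.1 (-0.570 to 0.686, median 0.110). Between wild type and double loss all same-numbered pairs did (0.686, 0.573 and 0.252). So did wild-type replicate 2 with double-loss replicate 3 (0.544) and wild-type replicate 3 with double-loss replicate 2 (0.383), while the other pairs of these groups were below 0. With the replicate block the counts were 3727, 3741, 3755, 3748, 5464, 5386, 1840, 3852 and 915 in the order above, all 305 named values kept their call, and the p53 list in double loss gave 0.051. The authors' other table was not run because its columns match no sample, and their probe values give no list or named gene. The chip could not be a block across chips. Signal over background limited the tests to 10372 of 30854 genes.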

Other observations

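The tests of chromosome 8 were written before the values they use were computed, after the median of the chromosome had been seen; of their settings, leaving out the brightest arrays was chosen only after the data were seen.

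Genes that changed in all 3 loss groups against wild type were counted apart. They numbered 247 up and 248 down, where independent lists would give 62 and 60, and a further 461 passed in all 3 with mixed directions. All 3 comparisons use the same wild-type arrays, so the excess is not taken as an effect common to the losses. At least 2-fold in each were 39 up and 27 down. Examples, chosen after their values were seen, are Camk2n1, an inhibitor of a calcium-dependent kinase (log2 fold change 2.22 in Lin28a loss, 2.04 in Lin28b loss and 1.86 in double loss), and Casp9, the initiator caspase of the mitochondrial pathway (1.35, 1.38 and 1.18). Down were Slc40a1, the iron exporter (-1.78, -1.74 and -1.22), Spry4, a feedback inhibitor of growth factor signalling (-1.44, -1.62 and -2.32), and the ecto-nucleotidase Nt5e (-1.16, -1.79 and -1.98). The imprinted RNA Meg3 had -2.86, -2.74 and -2.70.

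The Y-linked gene Ddx3y had a mean log2 intensity of 6.51 in wild type, 6.94 in Lin28a loss, 8.06 in Lin28b loss and 7.53 in double loss, without passing detection on any array, and Kdm5d and Uty stayed at background.

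The third pattern is that genes of chromosome 8 stood higher in both single-loss groups: of 376 genes 152 rose and 26 fell in Lin28a loss and 148 rose and 32 fell in Lin28b loss, while 41 rose and 90 fell in double loss. Normalization or array brightness is argued against by a median that stayed at 0.220 or above, relative to all genes, under cyclic loess, median scaling and without the brightest arrays. The brightness of the genes is argued against by 0 of 10000 draws of genes of other chromosomes matched on mean expression that reached both medians. An extra copy in part of the cells of both lines is consistent with a median of at least 0.194 on either side of the middle gene of the chromosome, although the last 93 genes had only 0.048 in Lin28a loss against 0.230 in Lin28b loss, so the copy may not span the whole chromosome there. No karyotype is given, and a biological effect of Lin28 on the chromosome was not tested.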
